A study of Mus musculus with 5 samples.

How the data were processed

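Small RNA from the hippocampi of knock-in mice carrying human BDNF (hBDNF, 129/Sv strain, 8 weeks old) was profiled on 5 2-colour miRNA arrays. Each array held RNA of 1 Met/Met mouse and 1 Val/Val mouse, so that 5 mice of each genotype were compared in 5 array pairs. Per the labels, Met/Met RNA carried Cy3 and Val/Val RNA carried Cy5 on every array, with no dye swap, so that a difference between genotypes and a difference between dyes cannot be separated in these values.

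The deposited scanner values are linear intensity values, 1 mean foreground value and 1 SD of intensity per spot and channel. Per the file headers the channels are called Test and Cntrl, and neither is tied to a dye or a genotype. The sample titles and the column names would make Test the Met/Met channel. The Cntrl channel had the higher signal on empty spots, and if that channel were Cy3 the labelling text would make Cntrl the Met/Met channel. The ratio is therefore given as Test over Cntrl throughout, and its direction between genotypes is not settled. The deposited background columns hold 0 on every spot, so the foreground intensity was not background-corrected. The scanning and quantification software is not given in the sources used here. The deposited series table holds log2 ratios of Test over Cntrl made by the authors, with column medians of -0.04, -0.02, -0.03, -0.03 and -0.05 for arrays 1 to 5. Over bright miRNAs these log2 values correlated with the ratios computed here at r = 0.981 to 0.995, and over all miRNAs at 0.773 to 0.926 (across miRNAs, which are not replicates). How the authors removed the intensity trend is not given in the sources used here. In the record of units the mean intensity columns were entered as other, because the deposited values of 1000 or more carry a comma as a digit separator.

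Each array had 3968 spots, with 569 mouse miRNA probes of 6 spots each, 5 probes for 5S rRNA of 4 spots each, 250 empty spots and 44 other control probes. Values were corrected per channel with normexp (offset 50) and normalized within each array by loess (span 0.3, control spots at weight 0) in limma 3.58.1 under R 4.3.3, and the spots of a probe were averaged. A miRNA was kept when it exceeded the 95th percentile of the empty spots in 1 channel on at least 3 arrays. This kept 568 of 569 probes, so the filter had almost no effect. The mean log2 ratio over the 5 arrays was tested against 0 with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment at 0.05. Because each ratio is taken within an array, the array is the block that pairs the mice.

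The analysis was tested on simulated data with 569 miRNAs, of which 100 were changed, in 20 simulations. Of changes of 0.5 on the log2 scale 85.6% were recovered, of changes of 1 on that scale 97.2%, with 5.19% false among the calls. Of the changed miRNAs, called or not, 99.9% had the right sign. The noise was independent between miRNAs and changes were added after background correction. Patterns shared within an array and the effect of the offset on weak signals were thus left out. Smaller changes were not simulated, and only 4 of the 568 miRNAs tested had a measured mean beyond 0.5 in either direction. The number of arrays limits the precision.

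Before the data were examined, 17 miRNA lists (brain cell types, activity-dependent miRNAs, reported regulators of Bdnf, miRNA families and genomic clusters, other tissues, and GC-rich probes prone to array artefacts), the tests, most alternatives and the rule for naming miRNAs were fixed. Lists were tested with limma's camera (correlation 0.01, and estimated), with fry beside it. The rule names miRNAs past the threshold on all 5 arrays in 1 direction. As fewer than 10 passed, it adds the 8 with the smallest p in each direction, miR-146a and miR-146b, and up to 4 members per list with the largest absolute mean log2 ratio. A miRNA was called bright at 500 or more intensity units above the median empty spot in at least 1 channel on at least 3 arrays. It was called dim when under 100 units in both channels on all arrays. Both limits were chosen after the values were seen.

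Alternatives fixed in advance were no background correction, subtraction of the empty-spot median (floor 1), in place of a local background that is 0, an offset of 16, median centring in place of loess, loess on detected miRNA spots alone, scale normalization between arrays, the median of repeat spots, no filter, detection in both channels on all arrays, the series table, eBayes with trend and robust settings, a fit of 10 unpaired channels and leaving out each array. Chosen after the data had been seen were bright miRNAs alone, array weights, the 5S rRNA ratio as a covariate, array 3 with its sign turned (in camera also with an estimated correlation), and loess on bright spots. Random lists, bootstrap intervals (2000 draws for array pairs, 1000 for residual correlations) and all sign patterns used fixed seeds or full enumeration. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15. Genome positions of the miRNAs were not used here.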

Results

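The arrays compared hippocampal miRNAs of mice homozygous for the Met or the Val form of human BDNF, a neurotrophin whose Val66Met variant alters its sorting and activity-dependent release. The 5 pairs, each of 1 Met/Met and 1 Val/Val mouse, were hybridised, 1 pair per array. The median miRNA signal lay between 63.9 and 186 intensity units in the Test channel and between 411 and 457 units in the Cntrl channel. The median empty spot lay between 31.4 and 45.5 units in Test and between 208 and 360 units in Cntrl. Of 569 miRNA probes, 410 exceeded the empty spots in both channels on all 5 arrays, and 188 were bright. The first count was limited by the Cntrl channel of array 5, where 411 probes exceeded the empty spots. In each other channel 527 to 569 did.

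The first question was which miRNAs differ between the genotypes. All ratios are Test over Cntrl: if Test is the Met/Met channel, as the sample titles imply, a positive value is higher in Met/Met, and if Cntrl is, as the dyes would imply should Cntrl be Cy3, it is higher in Val/Val. miR-146b, a brake on NF-kB signalling, had a log2 ratio of 0.27 ± 0.10 (SD, n = 5 arrays) and was higher in Test on 5 of 5 arrays, with a limma adjusted p of 0.0776. miR-337-3p of the Dlk1-Dio3 imprinted region had a log2 ratio of 0.22 ± 0.06 (SD, n = 5), and miR-342-3p one of 0.24 ± 0.10 (SD, n = 5). The other arm of the miR-337 hairpin, miR-337-5p, is outside the naming rule. It was bright and stood at -0.17 (limma adjusted p of 0.152). On the other side, miR-197 had a log2 ratio of -0.31 ± 0.07 (SD, n = 5), miR-328 one of -0.28 ± 0.06 (SD, n = 5) and miR-700 one of -0.53 ± 0.17 (SD, n = 5), each lower in Test on 5 of 5 arrays. None of the 568 miRNAs tested passed an adjusted p of 0.05 in limma, where the smallest adjusted p was 0.0577, shared by miR-197, miR-328 and miR-700. At an unadjusted p under 0.05 stood 110 miRNAs, 49 higher and 61 lower in Test, against 28.4 by chance. Which side held more depended on the processing, with 61 higher and 38 lower without background correction, 39 and 28 with the empty-spot median subtracted, 39 and 32 with detection in both channels, and 61 and 48 with array 3 turned.

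The remaining miRNAs with the smallest p on the higher side were miR-7a* at a log2 ratio of 0.27 ± 0.12 (SD, n = 5), miR-148a at 0.26 ± 0.16, miR-20b at 0.18 ± 0.08, miR-324-3p at 0.13 ± 0.04 and miR-483* at 0.12 ± 0.04. On the lower side they were miR-674 at a log2 ratio of -0.30 ± 0.15 (SD, n = 5), miR-532-5p at -0.25 ± 0.09, miR-712* at -0.24 ± 0.07, miR-190b at -0.20 ± 0.06 and miR-130b at -0.15 ± 0.03. Adjusted p in limma ran from 0.0577 to 0.152 over all 16. With median centring in place of loess, which leaves the trend of ratio with intensity in place, miR-328 and miR-674 turned to log2 ratios of 0.18 and 0.11. With the empty-spot median subtracted and in the series table miR-197 stood at -0.63 and -0.66, miR-712* at -0.52 and -0.50 and miR-190b at -1.52 and -0.82. Of the 16, 9 were not bright (500 units or more above the empty spots): miR-337-3p, miR-20b, miR-324-3p, miR-483*, miR-197, miR-700, miR-712*, miR-130b and miR-190b. miR-190b was near background, at 2.95 units in Test and 32.2 in Cntrl. miR-197 stood at 47.4 units above the empty spots in Test and 139 in Cntrl and miR-700 at 112 and 310, whereas miR-328 stood at 2802 and 4000. Without array 3, miR-146b, miR-328, miR-532-5p, miR-674* and miR-30e* passed the threshold (adjusted p = 0.0422 for each in limma, the last pair outside the naming rule and chosen after their values were seen), and without arrays 1, 2 or 4 the count at an unadjusted p under 0.05 was 58, 71 or 67. Among bright miRNAs alone, 0 passed in limma and 29 were at an unadjusted p under 0.05, 12 higher and 17 lower.

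**Figure D1:**
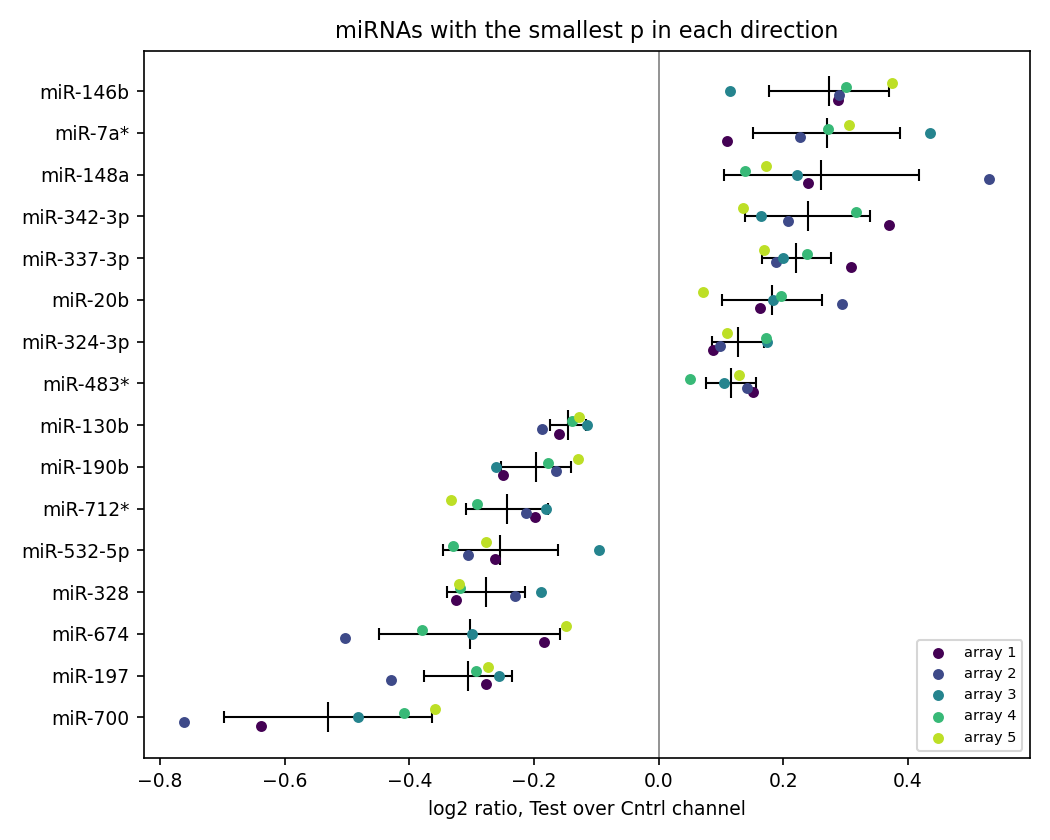
Log2 ratio of Test over Cntrl (x axis) for the 8 miRNAs with the smallest p in each direction (rows), with 1 point per array, a bar at the mean and whiskers of 1 SD (n = 5 arrays). All points of a row lie on one side of 0, from -0.76 for miR-700 on array 2 to 0.53 for miR-148a on array 2.

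miR-146b was set as a question of its own, because published work on this mouse line is remembered to have followed it. Whether that work drew on these same arrays was not checked, so the choice cannot be taken as independent of these values. Its target (UGAGAACUGAAUUCCAUAGGCU) had log2 ratios of 0.29, 0.29, 0.11, 0.30 and 0.37 on arrays 1 to 5, at 2563 units above the empty spots in Test and 2511 in Cntrl. An exact two-sided sign-flip permutation test over the 5 arrays gave p = 0.063, the smallest that 5 arrays allow. Any miRNA with 1 sign on all 5 arrays, as 112 of 568 had, reaches this value. It therefore adds nothing to the shared sign. miR-146a, which differs from it by 2 bases, had a log2 ratio of 0.14 ± 0.17 (SD, n = 5), higher in Test on 5 of 5 arrays, with a limma adjusted p of 0.311. With the sign of array 3 turned, miR-146b stood at 0.23 with a limma adjusted p of 0.177. Tested among bright miRNAs alone, miR-146b had a limma adjusted p of 0.231. Without array 1, 2 or 4 the smallest limma adjusted p of any miRNA was 0.210, 0.198 or 0.320. miR-146b passed the threshold with median centring, at 0.67, without array 3, at 0.31, and in 2 settings chosen after the data were seen, array weights at 0.29 and the 5S covariate at 0.23. Median centring leaves the trend of ratio with intensity in place. In that setting 248 miRNAs passed, so it does not single out miR-146b.

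The second question was whether miRNAs of a cell type, family or cluster shifted together. The 5 members of the miR-146 and NF-kB list all had positive means, with a median log2 ratio of 0.12, and miR-21 stood at 0.12 ± 0.40 (SD, n = 5) and miR-155 at 0.047 ± 0.19. Of the 6 miRNAs of microglia and leukocytes 4 were not bright, and 2 (miR-146a and miR-155) are shared with that list. All had positive means, with miR-150 at 0.28 ± 0.27 (SD, n = 5) and miR-223, a myeloid miRNA, at 0.21 ± 0.25. Neither miR-155 nor miR-223 was bright. Among 17 neuron-enriched miRNAs 6 means were positive and 11 negative, with miR-383 at -0.48 ± 0.32 (SD, n = 5) and miR-9, a neurogenic miRNA, at -0.17 ± 0.07, and the direction of this list and of miR-9 reversed with median centring. None of the 17 lists passed limma's camera. In limma's fry, which does not compare a list with other miRNAs, the smallest adjusted p for a shift in 1 direction was 0.568, and for change in either direction the neuron-enriched list passed with an adjusted p of 0.00515. In camera that list had an adjusted p of 0.461, and an adjusted p = 0.990 with an estimated correlation. Its call in fry was lost without array 1, 2 or 4 (adjusted p of 0.439, 0.0719 and 0.114), with array 3 turned (0.277) and among bright miRNAs (0.367). The smallest adjusted p in camera was 0.237, for the miR-146 list and for microglia and leukocytes, and both had an adjusted p of 0.990 with an estimated correlation. With the sign of array 3 turned, these 2 lists reached an adjusted p of 0.0451 in camera, but an adjusted p = 0.778 with an estimated correlation. With the 5S covariate their adjusted p was 0.750 and 0.589, and without array 5 it was 0.574 for each.

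Within the lists no member rose or fell at an adjusted p under 0.05 over all miRNAs. Adjusted over the list alone, 1 member passed in each of 3 lists, all higher in Test: miR-146b in the miR-146 list, miR-20b in the miR-17 clusters and miR-337-3p in the Dlk1-Dio3 clusters. This adjustment takes no account of the 17 lists, and over all miRNAs their limma adjusted p was 0.0776, 0.135 and 0.0579. miR-146b had been set as a question beforehand, though from remembered work that may rest on these same arrays, and miR-20b and miR-337-3p were not bright. The other arm of miR-337-3p, miR-337-5p, stood at -0.17. Of the activity-dependent miRNAs 6 of 9 means were positive, with miR-132, which CREB induces, at 0.16 ± 0.14 (SD, n = 5), miR-134 at -0.18 ± 0.21, miR-485* at -0.16 ± 0.11 and miR-485 at -0.11 ± 0.27. Among 12 miRNAs reported to target the Bdnf 3' UTR 8 means were positive, with miR-195 at 0.15 ± 0.11 (SD, n = 5), miR-15a at 0.11 ± 0.19 and miR-16 at 0.10 ± 0.13. The remaining neuron-enriched miRNAs named were miR-330, which was not bright, at 0.16 ± 0.09 (SD, n = 5) and miR-129-3p at -0.21 ± 0.39, which reversed with median centring.

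The astrocyte list had 2 positive and 4 negative means, with miR-29a at -0.27 ± 0.49 (SD, n = 5), miR-29c at -0.24 ± 0.48 and miR-29b at -0.12 ± 0.50, all reversed with median centring, and miR-23a at 0.096 ± 0.09. The oligodendrocyte list had 2 positive means of 3, with miR-338-5p at 0.26 ± 0.40 (SD, n = 5), miR-338-3p at 0.11 ± 0.51 and miR-219 at -0.15 ± 0.17, or -0.079 without array 2. Vascular miRNAs had 3 positive means of 4, with miR-126-5p at 0.41 ± 0.37 (SD, n = 5), miR-126-3p at 0.076 ± 0.07, miR-143 at 0.068 ± 0.13 and miR-145 at -0.046 ± 0.33. Of the erythrocyte miRNAs, miR-451 stood at 0.42 ± 0.65 (SD, n = 5), or 0.21 without array 2, miR-486 at 0.044 ± 0.37 and miR-144 at -0.0076 ± 0.06. In the choroid plexus, ependyma and epithelium list 9 of 14 means were positive, with miR-448 at 0.62 ± 1.05 (SD, n = 5), miR-204 at 0.29 ± 0.49, miR-34b-3p at 0.25 ± 0.44 and miR-211 at 0.13 ± 0.11, the first 3 carried by array 5 (0.16, 0.082 and 0.068 without it). Of the miRNAs named for these lists, miR-219, miR-126-5p, miR-144 and miR-211 were not bright.

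Families and clusters gave medians near 0. The let-7 family had 4 positive and 5 negative means, with miR-98 at 0.17 ± 0.64 (SD, n = 5), let-7a at -0.15 ± 0.28, let-7e at 0.074 ± 0.30 and let-7i at 0.057 ± 0.05. The miR-30 family had 1 positive and 4 negative means, with miR-30e at -0.082 ± 0.54 (SD, n = 5), miR-30b at -0.075 ± 0.13 and miR-30a at -0.040 ± 0.30, all reversed with median centring. In the miR-17 clusters 7 of 12 means were positive, with miR-92a at 0.25 ± 0.33 (SD, n = 5), miR-93 at -0.26 ± 0.20 and miR-106b at -0.11 ± 0.28. In the Dlk1-Dio3 clusters 24 of 46 means were positive, with miR-668 at -0.25 ± 0.24 (SD, n = 5), miR-380-3p at 0.23 ± 0.38 and miR-496 at 0.22 ± 0.23, the last 2 not bright. The Hox-cluster list had 3 positive means of 6, with miR-10b at 0.049 ± 0.10 (SD, n = 5), miR-196a at -0.044 ± 0.06 and miR-196b at 0.040 ± 0.06, none of its members bright. The muscle list had 2 positive means of 4, with miR-1 at 0.66 ± 1.31 (SD, n = 5), or 0.27 without array 5, miR-133b at -0.13 ± 0.13 and miR-133a at -0.12 ± 0.17, the last 2 not bright, and at -0.085 and -0.052 without array 2. The list of GC-rich probes had 3 positive means of 9, with miR-720 at -0.48 ± 1.01 (SD, n = 5), or -0.034 without array 5, miR-690 at -0.40 ± 1.25, or 0.066 to -0.79 with 1 array left out, miR-709 at -0.34 ± 0.34 and miR-671-5p at 0.12 ± 0.27. The name of this list does not describe miR-690, whose target holds fewer G and C than A and U bases. With median centring let-7a, miR-93, miR-106b, miR-10b, miR-196b, miR-690 and miR-709 changed sign, as did miR-134, miR-485, miR-485*, miR-145, miR-155 and miR-211 in the lists above. In camera the let-7, neuron-enriched, astrocyte, miR-30, miR-17 and GC-rich lists as a whole turned from lower to higher. The choroid plexus list turned from higher to lower.

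The third question was whether the 5 arrays ran the same way. Across the 568 miRNAs, which are not replicates, the correlation between array pairs ranged from -0.56 (arrays 3 and 5) to 0.63 (arrays 1 and 4), with a median of 0.29, and 2 of the 10 pairs were below 0, the second being arrays 1 and 3 at -0.30. The direction of array 3 relative to the others is therefore not settled. Array 5 had the widest spread of ratios over bright miRNAs, with an SD of 0.61 against 0.22 to 0.36 on the others. miR-1 had log2 ratios of 1.53, -0.11, -1.04, 0.69 and 2.26 on arrays 1 to 5, and miR-690 had -0.74, -0.15, 1.20, -0.04 and -2.24. The 5S rRNA probes, controls outside the tests, had median log2 ratios of -1.14, -0.27, 0.72, -0.11 and -2.05. With the sign of array 3 turned the median correlation was 0.39, but 2 of the 10 pairs were still below 0 (arrays 2 and 3 at -0.25, arrays 3 and 4 at -0.17). In that setting 0 miRNAs passed in limma with 109 at an unadjusted p under 0.05.

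**Figure D2:**
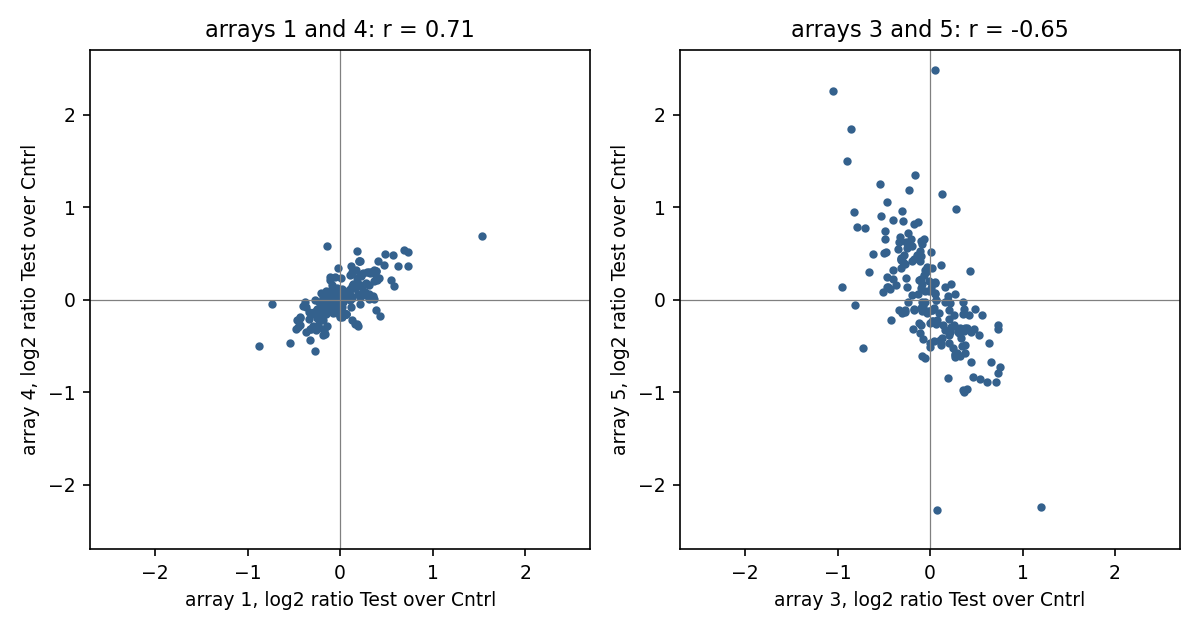
Log2 ratios of Test over Cntrl of bright miRNAs (1 point each, 188 in all) on arrays 1 and 4 (left) and on arrays 3 and 5 (right), with equal scales on both axes. The correlation across these miRNAs is 0.71 on the left and -0.65 on the right.

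**Figure D3:**
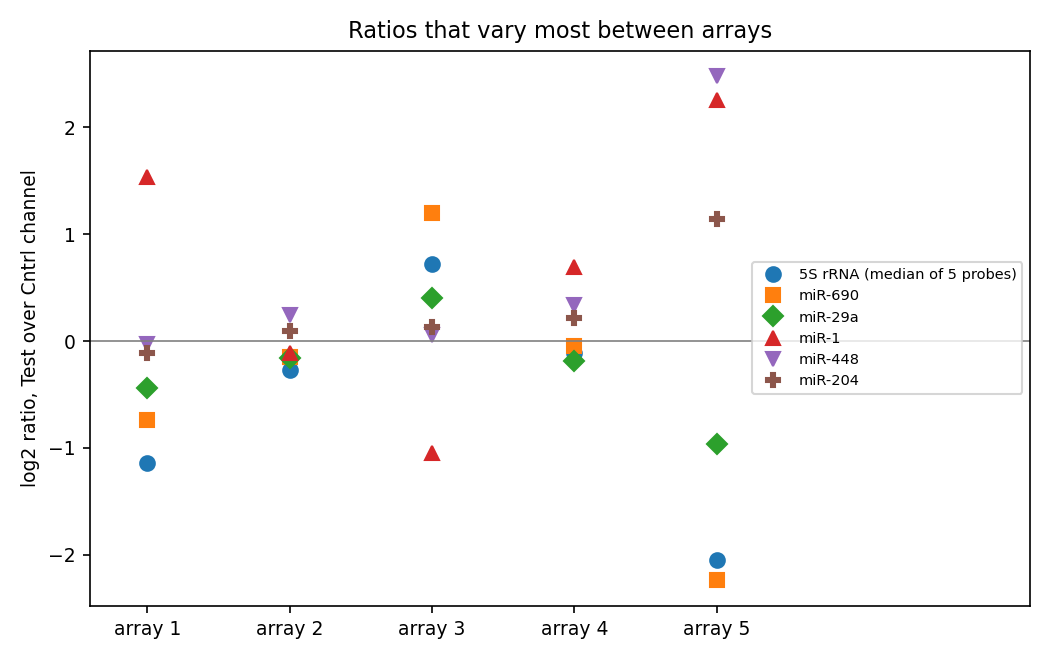
Log2 ratio of Test over Cntrl (y axis) on each of the 5 arrays (x axis) for the median of the 5S rRNA probes and for 5 miRNAs, 1 point per array. miR-690 follows the sign of 5S rRNA on each array, and miR-448 and miR-204 stand apart on array 5 at 2.48 and 1.15.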

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

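The tests on 5S rRNA, on exchanges within array 3, on dim probes, on hairpin arms and on the choroid plexus list were chosen only after the results they concern had been seen. Among 79 sets of 5 array values, 6 held an array far from the other 4, little more than the 5% or so of sets that chance gives. These were miR-148a on array 2 (0.53), miR-197 on array 2 (-0.43), miR-485 on array 5 (0.35), miR-448 on array 5 (2.48), miR-204 on array 5 (1.15) and miR-720 on array 5 (-2.27), all as log2 ratios. Many of the sets were named for the largest absolute means of their list, which favours sets with 1 far array. A further signal lay in control probes that no comparison tests: 5S rRNA had a median log2 ratio of -2.05 on array 5.

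Ratios on array 3 ran against those on arrays 1 and 5. Linear effects of GC content, length and end bases of the target were argued against as the whole cause, since the correlation of arrays 3 and 5 across bright miRNAs stayed at -0.67 after a fit on GC content and at -0.65 after one on length and end bases. Transcription of whole hairpins was argued against too. Over 20 hairpins with both arms bright, the arms' array 5 minus array 3 ratios correlated at -0.30 (95% bootstrap interval -0.66 to 0.12). In 13 the arms had opposite signs, as in miR-384-3p (-1.30) and miR-384-5p (1.14). By contrast, 31 pairs of near-identical targets all shared their sign, so other effects of target or probe sequence stay open. Such pairs overlap within families such as let-7 and are not independent observations. A candidate explanation is unequal 5S rRNA between the channels, as the 5S ratio took up 77.3% of the between-array variance and only 2 of 120 assignments of its values to arrays, the real one included, took up as much, but this was found and tested on the same arrays. Exchanged channel columns were argued against, since the median empty spot of array 3 had a log2 ratio of -2.44, of the sign of the other arrays (-3.52 to -2.48), but an exchange of the RNAs before labelling cannot be told apart from the rest: the highest correlation of array 3 with another array, 0.23 (0.06 to 0.39, array 2), counts against it, yet a dye effect common to all arrays could give that value even with an exchange, and genotype stays untested.

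More miRNAs had 1 sign on all 5 arrays (112 of 568, 19.7%) than the 6.25% of independent signs. A dye or background effect specific to each probe may contribute, since among 66 dim probes 30.3% had 1 sign (exact 95% interval 19.6 to 42.9%), 17 of the 20 being lower in Test, against 14.9% of bright probes. Without a dye swap, a genotype difference in the bright probes stays open beside it. Across bright miRNAs, which are not replicates, the ratio correlated negatively with the GC content of the target on all 5 arrays. The values of r were -0.10, -0.43, -0.15, -0.29 and -0.08 on arrays 1 to 5. Whether this contributes to the shared signs was not tested. Only 16 sign patterns of the 5 arrays exist, too few for a share under 0.05: the arrays as deposited gave 110 miRNAs at an unadjusted p under 0.05, reached by 1 of the 16, and the highest other pattern, with array 3 turned, gave 109.

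miR-448, miR-204 and miR-34b-3p, the bright members of the choroid plexus, ependyma and epithelium list, were high in the Test channel of array 5 (2.48, 1.15 and 0.97) and between -0.20 and 0.34 on the other 4. Slopes on 5S over arrays 1 to 4 predicted a median of -0.17 where 1.15 was observed, a gap of 1.31, but these miRNAs were singled out by their array 5 values, which favours a gap of this sign, so the 5S-related axis cannot be excluded. RNA of choroid plexus or ependyma in one of the 2 RNAs of array 5 is a possible explanation, but the list drew attention by these very values. Its 11 dimmer members, miR-200 and miR-449 miRNAs among them, averaged -0.22 on that array, at percentile 0 of 10000 random lists matched on signal, opposite to what this source would give, though members so near background exclude nothing. miR-204 differs by 1 base from miR-211, also on the list, and a difference between the genotypes was not tested as an explanation for these values on 1 array.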

How the results depend on the processing

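Array weights, the 5S rRNA covariate, the bright filter, array 3 turned and loess on bright spots were chosen after the data had been seen, most of them after 0 miRNAs had passed, so their counts are not the main result. Against 0 miRNAs past the threshold and 110 at an unadjusted p under 0.05, an offset of 16 gave 2 past it (miR-197 and miR-700), the deposited log2 ratios also 2 (the same miRNAs), the trend and robust test 4 (miR-197, miR-700, miR-712* and miR-190b), and median centring 248, with 295 at an unadjusted p under 0.05 and 9 lists past camera. The miRNAs passing in the first 3 of these settings were all lower in Test and not bright. Of the 20 dim probes with 1 sign on all 5 arrays, 17 were also lower in Test. Median centring leaves the trend of ratio with intensity in place by construction, and it moved the median of all ratios to -0.04. Array weights gave 21 past the threshold and 170 at an unadjusted p under 0.05, and the 5S covariate 34. Counts at an unadjusted p under 0.05 were 67 with subtraction of the empty spots, 71 with detection in both channels, 29 for bright miRNAs (fewer miRNAs tested in both) and 6 with loess on bright spots, where the median ratio was -0.07 and the dim probes lay outside the fitted range. With array 3 turned 2 lists passed (miR-146 and microglia, adjusted p of 0.0451 each), but 0 did with the correlation estimated (adjusted p of 0.778 each), and with the 5S covariate these 2 stood at 0.750 and 0.589 and without array 5 at 0.574 each. At an unadjusted p under 0.05, 49 miRNAs were higher and 61 lower in Test, and the balance turned with no background correction (61 and 38), subtraction of the empty spots (39 and 28), an offset of 16 (52 and 50), detection in both channels (39 and 32), array 3 left out (72 and 68), the 5S covariate (85 and 76) and array 3 turned (61 and 48). The call of the neuron-enriched list in fry, for change in either direction (adjusted p of 0.00515), was kept without array 3 (0.000928) and without array 5 (0.00325). It was lost without array 1 (0.439), array 2 (0.0719) or array 4 (0.114), with array 3 turned (0.277) and among bright miRNAs (0.367). Other lists passed fry as well when array 3 or array 5 was left out. Without array 3 these were the activity-dependent, miR-146, miR-17 and Dlk1-Dio3 lists, and without array 5 the miR-17 and Dlk1-Dio3 lists. Without the array as a block that pairs the mice, 1 miRNA (miR-197) passed and 53 were at an unadjusted p under 0.05. Leaving out an array gave 0 to 5 miRNAs past the threshold, 58 to 140 at an unadjusted p under 0.05, 0 lists past camera in each case and a median correlation of 0.21 to 0.49. Loess on detected miRNA spots and the absence of a filter changed almost nothing by construction and say nothing of stability. The miR-146b ratio was positive in all 22 alternatives, from 0.23 to 0.67, with an adjusted p in limma from 0.00192 (median centring) to 1.000 (loess on bright spots), and it passed with median centring (0.67), without array 3 (0.31, against a range of 0.25 to 0.31 over the arrays left out), with array weights (0.29) and with the 5S covariate (0.23). The constant sign of miR-146b was largely fixed in advance. All 5 array values were positive, so leaving out or weighting arrays could not reverse it, and several settings changed only the test or the filter. As to signal over background, 410 of the 568 miRNAs were above the empty spots in both channels on all arrays, a count limited by the Cntrl channel of array 5.

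Of 1619 values of the 75 other named miRNAs over the alternatives, 1472 kept their direction and side of the threshold, 68 kept their direction and passed it, and 79 changed sign; the causes were not tested. Without background correction the sign changed for miR-145 (0.013), miR-144 (0.012) and miR-30d (0.019). With subtraction of the empty spots the sign changed for miR-144 (0.15) and miR-196a (0.032). With an offset of 16 the sign changed for miR-144 (0.016). With median centring the sign changed for miR-328 (0.18), miR-674 (0.11), miR-129-3p (0.39), miR-9 (0.65), miR-134 (0.039), miR-485* (0.20), miR-485 (0.21), miR-155 (-0.12), miR-29a (0.53), miR-29c (0.52), miR-29b (0.56), miR-145 (0.41), miR-211 (-0.026), miR-10b (-0.088), miR-196b (-0.12), let-7a (0.67), miR-30e (0.52), miR-30b (0.68), miR-30a (0.65), miR-30d (0.66), miR-93 (0.0020), miR-106b (0.20), miR-206 (-0.050), miR-690 (0.22) and miR-709 (0.48). With scale normalization the sign changed for miR-30d (0.019) and miR-206 (-0.011). With array weights the sign changed for mmu-miR-486 (-0.0070), miR-30d (0.015) and miR-206 (-0.015). With the 5S covariate the sign changed for miR-1 (-0.0085), miR-21 (-0.067), miR-155 (-0.054), miR-29c (0.012), miR-29b (0.14), miR-486 (-0.097), miR-98 (-0.15), let-7e (-0.074), miR-30e (0.20), miR-30a (0.12), miR-30d (0.13), miR-106b (0.029), miR-206 (-0.12), miR-690 (0.27) and miR-671-5p (-0.019). With array 3 turned the sign changed for miR-134 (0.022), miR-485 (0.017), miR-338-3p (-0.16), miR-145 (0.14), miR-144 (0.026), miR-10b (-0.016), miR-196a (0.010), let-7a (0.012) and miR-380-3p (-0.041). With loess on bright spots the sign changed for miR-155 (-0.054), miR-10b (-0.035), miR-196b (-0.055) and miR-206 (-0.063). Among the 16 miRNAs of smallest p, moves by over 1.5 times that kept the sign were these. Without background correction miR-190b stood at -0.10, and with an offset of 16 at -0.32. With subtraction of the empty spots miR-324-3p stood at 0.25, miR-483* at 0.25, miR-197 at -0.63, miR-712* at -0.52 and miR-190b at -1.52. With median centring miR-146b stood at 0.67, miR-342-3p at 0.85, miR-7a* at 0.61, miR-20b at 0.28, miR-483* at 0.067, miR-148a at 0.63 and miR-532-5p at -0.052. In the deposited log2 ratios miR-197 stood at -0.66, miR-712* at -0.50, miR-190b at -0.82 and miR-130b at -0.22. With array 3 turned miR-337-3p stood at 0.14, miR-7a* at 0.096, miR-20b at 0.11, miR-324-3p at 0.059, miR-483* at 0.073, miR-148a at 0.17, miR-197 at -0.20, miR-700 at -0.34, miR-190b at -0.092 and miR-674 at -0.18. With loess on bright spots miR-324-3p stood at 0.041, miR-483* at 0.0033 and miR-130b at -0.22. For the 60 other named miRNAs, such moves are listed for each array left out. Without array 1 these were miR-15a (0.055), miR-21 (0.058), miR-143 (0.031), miR-145 (-0.16), miR-486 (0.10), miR-144 (-0.0050), miR-615-3p (-0.014), miR-206 (0.016) and miR-671-5p (0.060). Without array 2 these were miR-219 (-0.079), miR-223 (0.13), miR-145 (-0.013), miR-451 (0.21), miR-144 (-0.020), miR-10b (0.080), miR-196b (0.022), miR-30d (-0.014), miR-133b (-0.085), miR-133a (-0.052) and miR-206 (0.13). Without array 3 these were miR-134 (-0.10), miR-485 (-0.058), miR-1 (1.09), miR-21 (0.27), miR-155 (0.10), miR-29a (-0.43), miR-29c (-0.39), miR-29b (-0.29), miR-486 (0.14), miR-10b (0.021), miR-196a (-0.021), miR-98 (0.42), let-7a (-0.084), let-7e (0.15), miR-30e (-0.26), miR-30a (-0.14), miR-30d (-0.089), miR-92a (0.37), miR-106b (-0.20), miR-380-3p (0.12), miR-206 (0.083), miR-690 (-0.79) and miR-671-5p (0.21). Without array 4 these were miR-485 (-0.066), miR-15a (0.057), miR-338-3p (0.029), miR-145 (-0.029), miR-486 (0.079) and miR-30d (-0.013). Without array 5 these were miR-146a (0.092), miR-129-3p (-0.045), miR-485 (-0.22), miR-1 (0.27), miR-15a (0.16), miR-21 (0.025), miR-338-5p (0.12), miR-338-3p (0.30), miR-29a (-0.094), miR-29c (-0.056), miR-143 (0.035), miR-145 (-0.092), miR-144 (-0.027), miR-448 (0.16), miR-204 (0.082), miR-34b-3p (0.068), miR-10b (0.024), miR-196b (0.061), let-7a (-0.26), miR-30b (-0.026), miR-92a (0.15), miR-106b (-0.011), miR-380-3p (0.36), miR-720 (-0.034) and miR-671-5p (0.052). In the remaining settings these 60 had such moves in 34 cases with median centring, 28 with the 5S covariate, 27 with array 3 turned, 17 with loess on bright spots, 16 with array weights, 15 in the deposited log2 ratios, 13 without background correction, 12 with subtraction of the empty spots, 5 with scale normalization, 4 with an offset of 16 and 4 with the median of repeat spots. Over the settings that left out 1 array, the log2 ratio ran for miR-486 from -0.082 to 0.14, miR-338-3p from -0.031 to 0.30, miR-145 from -0.16 to 0.060, miR-144 from -0.027 to 0.011, miR-155 from -0.030 to 0.10, miR-29b from -0.29 to 0.062, miR-98 from -0.023 to 0.42, let-7e from -0.048 to 0.15, miR-30e from -0.26 to 0.12, miR-30a from -0.14 to 0.074, miR-30d from -0.089 to 0.099, miR-206 from -0.098 to 0.13 and miR-690 from -0.79 to 0.066.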

Other observations

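The strongest movers between arrays were not the miRNAs with the smallest p. The test favours this by construction, since it sets the mean against the spread between arrays. After miR-448 and miR-1, the highest log2 ratios on array 5 among bright miRNAs were those of miR-374 (1.84), miR-7b (1.49), miR-15b (1.35) and miR-199a-3p (1.25), and on array 3 miR-374 and miR-7b stood at -0.85 and -0.90. The lowest on array 5, after miR-720 and miR-690, were miR-31 (-0.995), miR-29c (-0.98), miR-29a (-0.96), miR-30e (-0.89) and miR-101a (-0.89). One axis held 68.4% of the variation of the 188 bright miRNAs, with loadings of 0.28, 0.09, -0.38, 0.14 and 0.87 on arrays 1 to 5. These miRNAs were chosen after their values were seen.

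miR-451, an erythrocyte miRNA, had log2 ratios of -0.14, 1.25, 0.74, 0.58 and -0.32 on arrays 1 to 5, while miR-144 of the same cluster stood between -0.08 and 0.07 at 14.4 units above the empty spots in Test and 41.2 in Cntrl. miR-126-5p of vascular cells had 0.82, 0.66, -0.05, 0.11 and 0.51, but was not bright, at 158 units above the empty spots in Test and 143 in Cntrl. The other arm of its hairpin, miR-126-3p, was bright and had 0.12, 0.05, 0.02, 0.02 and 0.17.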
